A study of Mus musculus with 12 samples.

How the data were processed

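Droplet single-cell RNA libraries and paired T cell receptor libraries were made from live CD4+ T cells sorted from the lungs of mice carrying TC-1 tumours, a mouse lung epithelial tumour line. The mice carried loxP-flanked Pdcd1, the gene of the checkpoint receptor PD-1, and a tamoxifen-inducible Cre with eGFP at 1 of the Foxp3 alleles, so that Tregs with and without the Cre shared each lung. Tamoxifen was given from day 0 to day 4, tumour cells were injected on day 12, and an isotype antibody or an anti-PD-1 antibody was given every 3 days after day 13, per the labels. The lungs were taken 14 days after the tumour cells. The 12 samples form 4 groups of 3, an isotype and an anti-PD-1 group for each kind of library. The labels number the samples 1 to 3 but name no animals, so p-values measure only the spread between these libraries.

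Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 3.2.1 were used with the mm10 build. The deposited tables give UMI counts per gene and cell, whole numbers that are not normalized, and the deposited annotation gives for each cell its library, UMI count, percent of mitochondrial UMIs, class and receptor sequence. The deposited percent of mitochondrial UMIs reaches 4.97%, and every one of the 41054 cells has a receptor sequence. Deposited normalized tables were not used here. Replicate 1 of both antibodies is in 1 table of 14652 genes, replicate 2 in another of 15834 and replicate 3 in a further table of 15705. The 13686 genes in all 3 tables were used, which hold 99.2% to 99.5% of the UMIs of each library. No gene of the tables is named for eGFP or Cre (0 rows), so the transgene was not measured. Of these genes, 99.7% matched 1 entry of the GENCODE M21 annotation of the same build, from which coordinates were taken. No column of per-sample counts was left unused.

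The deposited annotation puts each cell in 1 of 5 classes: Treg_Norm, Treg_KO, Tconv_PD1High, Tconv_PD1Low and Mki67High. Treg sums hold the Treg_Norm and Treg_KO cells, and Tconv sums, of conventional CD4 T cells, hold both Tconv classes. Cells of the cycling class Mki67High were kept out of both. No doublet calling was added here. More than 1 beta chain was listed for 7.41% of the cells.

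UMI counts were summed per library and class, and the sums were tested across libraries with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Treated and isotype sums were compared in Tregs and in Tconv. The difference between both effects was tested as an interaction with the library as a block. Treg_KO and Treg_Norm were compared with the library as a block, and their interaction with treatment was tested in the same model. The standard error of a log2 fold was taken as its size over the square root of the F statistic. CPM are TMM-scaled unless CPM of all UMIs are named. With 200 genes changed in simulated counts, 54.6% of those changed by a log2 fold of 1 were recovered in the Treg comparison of 9736 genes, and 93.7% of those changed by 2, with 14 false calls. At a log2 fold of 1, 78 of 100 changed genes were recovered in Tconv (11505 genes tested), 59 of 96 in the interaction (11384) and 82 of 97 between the Treg classes (8892). The simulated libraries were drawn independently, with no effect shared by same-numbered libraries and no other difference between classes. These shares therefore need not hold for the real comparisons.

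Before the data were examined, 31 gene lists were fixed and tested with camera of limma 3.58.1 (preset correlation 0.01, then an estimated correlation) and with fry, adjusted over the lists of a comparison. Lists with fewer than 3 measured genes were not tested. The genes named are Pdcd1, Foxp3 and, per comparison and direction, the 12 largest folds among genes past the threshold with a mean log2 CPM of at least 4 and the same direction in every numbered pair or library. Receptor, mitochondrial and ribosomal protein genes and numbered gene models are not named by this rule. Where fewer than 5 passed, the 5 of smallest p are named and said not to have passed, and up to 4 members per list are named by smallest p. Of the genes this rule names, some are not reported here.

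Shares of cells were compared by two-sided exact permutation tests on the 3 against 3 libraries, for which the smallest p is 0.1, with exact sign-flip tests on the numbered pairs, for which it is 0.25. A family of 9 shares was adjusted together. Of these, 4 were added after seeing the data: the Treg_KO share, the PD1High share and both shares of cells with a Pdcd1 UMI. The cycling share was taken as Mki67High cells among Treg-class and Mki67High cells with a Foxp3 UMI, after each cell was thinned to 2000 UMIs. Shallower cells were left out, 59 of 2297 Treg cells of the isotype group and 43 of 2408 of the anti-PD-1 group. A clone is a set of cells of 1 library with identical nucleotide sequences of all listed receptor chains. Clone shares were means over 100 subsamples of equal cell number per library. Intervals are exact binomial at 95% and, like the floor of 3 counts, cover counting error only.

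Deviations from the group means were compared between numbered libraries. Same-numbered isotype and anti-PD-1 libraries correlated across genes at 0.270 to 0.537 in Tregs and 0.375 to 0.717 in Tconv, all above 0.1, the limit at which the numbers, which come from the labels, were taken to pair the libraries. Replicates 2 and 3 also correlated across numbers, at 0.177 and 0.280 in Tregs and 0.388 and 0.392 in Tconv, and replicate 1 correlated negatively with both, so the check parts mainly replicate 1 from the others. The fit with the replicate number as a block is given beside a result where it changes a call. Between the Treg classes and in both interactions the number then took the place of the library, so classes of 1 library were not paired. Other alternatives were DESeq2 1.42.0, no TMM factor, no filter, leaving out each library, leaving out cells with UMIs of at least 2 markers of another lineage (65 to 100 cells per library), and Treg cells defined by a Foxp3 UMI. Alternatives added after seeing the data were 1 cell per clone, the highest cell of each gene left out, replicates 2 and 3 only or summed, the block with each of these but replicates 2 and 3 only, thinned cells, and for gene lists leaving out each library and Treg_Norm cells only. Treatment was also tested in each of the 5 classes, as a result added after seeing the data.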

Results

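Single-cell RNA and receptor libraries of lung CD4+ T cells were compared between tumour-bearing mice given an isotype or an anti-PD-1 antibody, with 3 RNA libraries in each group. The isotype libraries held 6935, 6485 and 6426 cells with 39137789, 31552284 and 30986539 UMIs in replicates 1 to 3. The anti-PD-1 libraries held 6942, 7390 and 6876 cells with 37396959, 36451906 and 34323824 UMIs. Median UMIs per cell ranged from 4251 to 5081. The deposited classes held 4030 Treg_Norm, 675 Treg_KO, 12115 Tconv_PD1High, 23440 Tconv_PD1Low and 794 Mki67High cells. Treg_KO cells numbered 81 to 172 per library, which limits what could be detected in them.

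Pdcd1, on chromosome 1 from 94038305 to 94052553 in mm10 on the minus strand, was lower in Treg_KO than in Treg_Norm cells of every library. It stood at 539.7 to 889 CPM of all UMIs in Treg_Norm cells and at 47.5 to 120.3 in Treg_KO cells. The share of cells with a Pdcd1 UMI was 63.3% to 84.7% in Treg_Norm and 13.4% to 22.9% in Treg_KO, at median depths of 5121 and 4240 UMIs per cell. In Tconv_PD1Low cells, a class named for low PD-1, it was 1.56% to 3.80% at a median depth of 4549, and in Tconv_PD1High cells it was 39.2% to 45.7%. Treg_KO cells thus had Pdcd1 UMIs more often than Tconv_PD1Low cells, whose low share may come from how that class was drawn. The labels do not say which exons the loxP sites flank, so Pdcd1 UMIs from libraries read at the 5' end need not report the deletion. Foxp3, the Treg lineage factor on chromosome X from 7573644 to 7595245, was detected in 48.2% to 54.6% of Treg_KO and 78.5% to 87.9% of Treg_Norm cells, against 0.836% to 3.03% of Tconv_PD1Low cells.

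**Figure D1:**
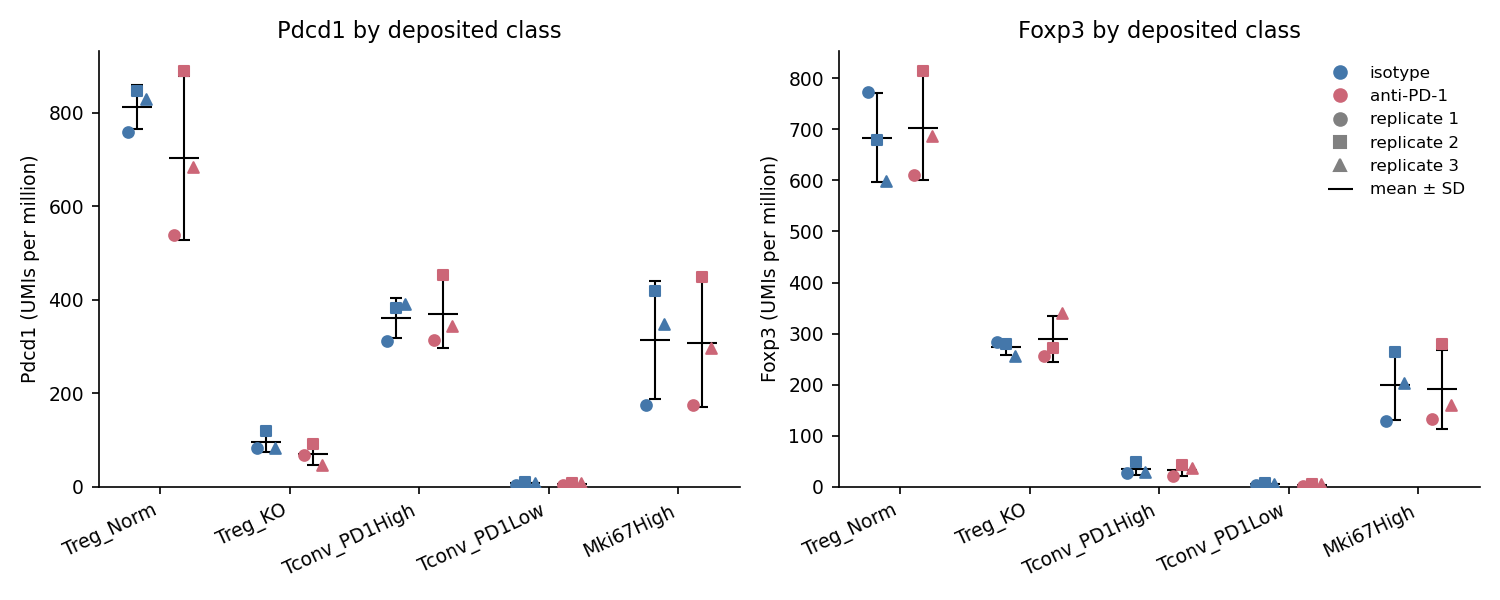
Pdcd1 (left) and Foxp3 (right) in CPM of all UMIs, summed over the cells of each deposited class in each library, with 1 point per library, colour for the antibody, and bars for the mean ± SD of 3 libraries. Pdcd1 lies at 539.7 to 889 in Treg_Norm and at 47.5 to 120.3 in Treg_KO, without overlap.

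The comparison of treated with isotype Tregs asked how the antibody changed the Tregs of the lung. No gene passed in the fit without the replicate block, so the named genes are given as values. Calca, the gene of calcitonin and a related neuropeptide, was at 26.8 ± 0.828 CPM in isotype and 14.1 ± 1.70 in anti-PD-1 Tregs (SD, n = 3 each), where 32 of the 49 UMIs of anti-PD-1 replicate 1 lay in 1 cell. Its log2 fold was -0.94 ± 0.14 (SE), lower in 3 of 3 numbered pairs. Tmem158, Dhrs3, Zcchc18 and Arrdc4 had log2 folds of -0.48 ± 0.13, -0.48 ± 0.12, -0.46 ± 0.14 and -0.66 ± 0.20. In the other direction, Gadd45g, a stress-induced growth arrest gene, was at 119.7 ± 9.24 and 161 ± 8.96 CPM, a log2 fold of 0.43 ± 0.10. Cldnd1, Card6, Mpp1 and Dock11 had log2 folds of 0.31 ± 0.10, 0.42 ± 0.14, 0.33 ± 0.11 and 0.31 ± 0.11. Pdcd1 was at 728 ± 57.6 and 622 ± 186 CPM (log2 fold -0.23 ± 0.20) and Foxp3 at 636 ± 87.2 and 649.8 ± 103 CPM (0.03 ± 0.15). All 12 had an adjusted p of 0.9999 in edgeR.

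By gene list, 11 of 26 lists passed camera in Tregs, 8 of them lower with treatment. These calls hang on anti-PD-1 replicate 1, in which Treg_KO cells made up 30.9% of the Tregs against 7.75% to 18.4% in the other libraries. Without it 1 list passed camera, B cell markers, and positive members were 7 of 18 in naive and central memory, 26 of 45 in interferon response and 11 of 18 in Treg suppression. Leaving out another library 4 to 13 passed. In Treg_Norm cells only, where Treg_KO cells play no part, 10 passed, all of the 11 but dissociation and heat-shock stress, and 0 with an estimated correlation. In all Tregs, in the Th2 list 8 of 9 measured members had negative log2 folds, among them Calca, the Th2 master factor gene Gata3 (-0.22 ± 0.09) and the IL-33 receptor gene Il1rl1 (-0.32 ± 0.18), with a camera adjusted p of 5.74e-05 and an adjusted p = 0.282 with an estimated correlation. In the interferon response list 36 of 45 members were negative, such as Rtp4 (-0.29 ± 0.14) and Oas1a (-0.30 ± 0.17), with a camera adjusted p of 0.000134. Negative folds also made up 14 of 15 members of class I antigen presentation (H2-T23 -0.24 ± 0.09, Tap1 -0.21 ± 0.11) and 13 of 18 of Treg suppression (Klrg1 -0.54 ± 0.25, Pdcd1lg2 -0.32 ± 0.15). They made up 12 of 18 of Treg identity (Ikzf4 -0.33 ± 0.13, Tnfrsf9 -0.36 ± 0.20) and, in sums without the cycling Mki67High cells, 20 of 27 of cell cycle (Tubb5 -0.21 ± 0.09). The camera adjusted p values of these 4 lists were 0.0122, 0.00146, 0.0221 and 0.0140. Interferon response and these 4 lists each had an adjusted p = 0.667 with an estimated correlation.

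Positive folds made up 16 of 18 members of the naive and central memory list, such as Rapgef6 (0.17 ± 0.10), with a camera adjusted p of 0.00937 and an adjusted p = 0.667 with an estimated correlation. They made up 7 of 11 of Tfh (Sh2d1a 0.47 ± 0.17, Il6ra 0.41 ± 0.22) and 19 of 26 of dissociation and heat-shock stress (Hsph1 0.51 ± 0.19, Jun 0.27 ± 0.10), which may reflect handling. Both had a camera adjusted p of 0.0221, and an adjusted p = 0.445 and 0.617 with an estimated correlation. Lists of lipid and energy metabolism did not pass, with camera adjusted p values of 0.993 for cholesterol synthesis, 0.435 for fatty acid synthesis and uptake and 0.519 for fatty acid oxidation. Lists of markers of other cells were also called lower in the same treated Tregs. Of B cell markers 5 of 7 were negative (Igkc -0.48 ± 0.18, H2-Ab1 -1.74 ± 0.53), with a camera adjusted p of 0.000468 and an adjusted p = 0.282 with an estimated correlation. Of macrophage and monocyte markers 5 of 6 were negative (Plac8 -0.92 ± 0.41), with a camera adjusted p of 0.0173 and an adjusted p = 0.617 with an estimated correlation. Plac8 UMIs lay in 60 of 556 Tregs of anti-PD-1 replicate 1 and in up to 382 of 1045, in isotype replicate 2. Only 0 to 4 cells per library, of any class, had UMIs of at least 2 macrophage markers, so the fall of Plac8 need not reflect other cells. Over all genes 0 members of these lists passed, and adjusted over the list alone 1 passed, Calca in the Th2 list. With the replicate block camera called 14 lists, glycolysis, co-inhibitory and exhaustion and dendritic cell markers besides these 11, and 0 with an estimated correlation. Adjusted over the list alone in that fit, other genes passed beside Calca, those not named above named after their values were seen. They were, with log2 folds, Il1r2 -0.41, Klrg1 -0.58, Havcr2 -0.54, Ebi3 -0.47 and Pdcd1lg2 -0.32 in Treg suppression, Igkc -0.48, Cd79b 0.40, H2-Ab1 -1.66, H2-Aa -1.12, H2-Eb1 -0.69 and Cd74 -0.46 in B cell markers, Plac8 -0.97 and Lyz2 1.64 in macrophage and monocyte markers, Zbtb46 -0.48 and Bst2 -0.23 in dendritic cell markers and Il2 6.09 in Th1 and cytotoxic.

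**Figure D2:**
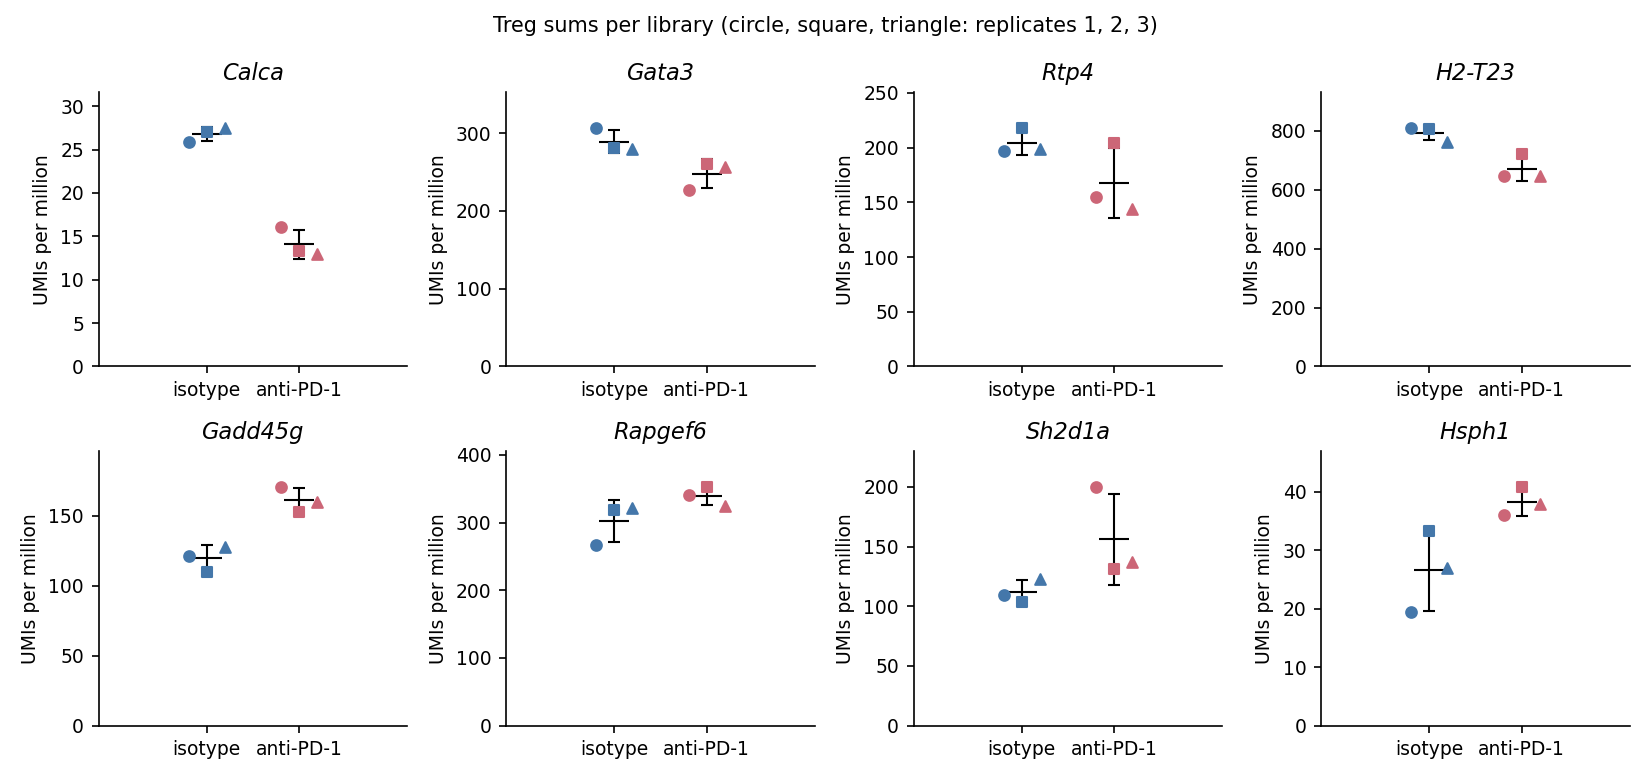
CPM (TMM-scaled, linear axes from 0) of 8 named genes in the Treg sums of each library, with colour for the antibody, marker shapes for replicates 1 to 3 and bars for the mean ± SD of 3 libraries. Calca lies at 26.8 ± 0.828 in isotype and 14.1 ± 1.70 in anti-PD-1 Tregs, and none of the 8 genes passed the adjusted threshold.

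For the Treg comparison edgeR called 0 of 9768 genes, with 178 at an unadjusted p under 0.05, and DESeq2 called 2, Trav8n-2 (2.07) and Trav8-1 (1.96) by log2 fold. The 178 are a smaller share than 0.05, the share that no effect would give on average, so the unblocked fit may be conservative. The replicate block left 554 of 9996 genes at an unadjusted p under 0.05. With the replicate number as a block edgeR called 4: Il2 (log2 fold 6.09 ± 0.51), Trav8-1 (1.94 ± 0.21) and Trav8n-2 (1.96 ± 0.24) higher and the chemokine gene Ccl1 (-3.55 ± 0.25) lower, with adjusted p of 0.00795, 0.0190, 0.0348 and 0.00118. These were named after their values were seen, and 147 of the 149 Il2 UMIs of anti-PD-1 replicate 2 lay in 1 cell. Of the Ccl1 UMIs of isotype replicates 2 and 3, 113 of 125 and 132 of 135 lay in 1 cell. With replicates 2 and 3 of each antibody summed, since they share receptors, edgeR called 0 genes without the block (64 at an unadjusted p under 0.05, DESeq2 not run). With the block it called 12 on replicate 1 and the sum of each antibody, which leave 1 residual degree of freedom, with Trav8-1, Trav8n-2 and Ccl1 among them, while Il2 was below the filter.

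In conventional CD4 T cells, which carry PD-1 without the Cre, no gene passed the same comparison either. The heat-shock genes Hsph1 and St13 had log2 folds of 0.47 ± 0.11 and 0.25 ± 0.06. The galectin gene Lgals3 was at 28.0 ± 6.19 CPM in isotype and 45.2 ± 7.65 in anti-PD-1 Tconv (SD, n = 3 each), a log2 fold of 0.69 ± 0.18. The phosphatase gene Ptpn6 and Ahsa2 had log2 folds of 0.34 ± 0.09 and 0.28 ± 0.10. Crybg1, Ccdc107, Lilr4b, Ell2 and Nup98 had log2 folds of -0.27 ± 0.07, -0.28 ± 0.08, -0.59 ± 0.18, -0.21 ± 0.07 and -0.20 ± 0.06. Pdcd1 was at 134 ± 16.9 and 135 ± 33.8 CPM (0.02 ± 0.19), and Foxp3 had -0.13 ± 0.38. All 12 had an adjusted p of 0.9999 in edgeR.

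Of 29 lists, 7 passed camera in Tconv, and each of them had an adjusted p = 0.901 with an estimated correlation. Without anti-PD-1 replicate 1, 2 of them still passed, cell cycle and interferon response, and without isotype replicate 2, 1 did, cell cycle, against 4 to 6 without another library. Negative folds made up 37 of 45 members of interferon response (Ifi27l2a -0.21 ± 0.09, Oas1a -0.18 ± 0.09), 14 of 18 of Treg identity (Tnfrsf18 -0.23 ± 0.10, Tnfrsf4 -0.26 ± 0.13) and 14 of 18 of Treg suppression (Tigit -0.22 ± 0.12, Areg -0.48 ± 0.27). Their camera adjusted p values were 2.26e-06, 0.000681 and 0.0172. They made up 10 of 13 of Th17 (Tmem176b -0.35 ± 0.29), 10 of 12 of Th2 (Il5 -1.85 ± 1.02) and 4 of 6 of CD8 T and NK markers (Gzmk -0.33 ± 0.18), with camera adjusted p values of 0.0172, 0.0173 and 0.0408. Of the Il5 UMIs of isotype replicate 3, 210 of 223 lay in 1 cell. In the cell cycle list, in sums without the cycling Mki67High cells, 27 of 38 were positive, such as Mcm5 (0.19 ± 0.08) and Tyms (0.18 ± 0.11), with a camera adjusted p of 0.000681. Over all genes, and adjusted over the list alone, 0 members of these lists passed. With the replicate block 0 passed over all genes, and adjusted over the list alone, by log2 fold and, where not named above, named after their values were seen, Il17a -0.46, Il17f -1.19, Tmem176b -0.38, Tmem176a -0.35 and Ltb4r1 -0.59 passed in Th17 and Irf7 -0.22 and Ifi27l2a -0.20 in interferon response. So did Tnfrsf18 -0.23 in Treg identity, Il5 -1.99 in Th2, Gzmk -0.33 in CD8 T and NK markers, Atf3 -0.42 and Hsph1 0.46 in dissociation and heat-shock stress, Fas -0.30 in apoptosis and Ighm 0.25 in B cell markers. For Tconv edgeR called 0 of 11496 genes, with 180 at an unadjusted p under 0.05, and DESeq2 called 0. The replicate block left 721 of 11709 genes at an unadjusted p under 0.05, so here too the unblocked fit may be conservative.

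The interaction asked whether the treatment effect differed between Tregs and Tconv, with positive values for a higher effect in Tregs. The growth factor gene Areg had a log2 difference of 0.65 ± 0.14, Tubb2b of 1.23 ± 0.31, Fbrsl1 of 0.50 ± 0.13, Arl5c of 0.36 ± 0.10 and Nup98 of 0.32 ± 0.08. The invariant chain gene Cd74 had -0.57 ± 0.12, Pglyrp1 -0.34 ± 0.09, Hvcn1 -0.52 ± 0.14, Hspa4l -0.80 ± 0.22 and Sytl3 -0.51 ± 0.14. Pdcd1 had -0.26 ± 0.08, lower in 3 of 3 pairs, and Foxp3 0.17 ± 0.28. None of them passed in edgeR, which called 0 of 11719 genes, with 373 at an unadjusted p under 0.05, and DESeq2 called 1, Trav8n-2 (2.03), named after its value was seen. Leaving out anti-PD-1 replicate 1 gave 1 call and leaving out anti-PD-1 replicate 2 gave 5. Of 29 lists 6 passed camera, 3 with the replicate block in place of the library block and 0 with an estimated correlation. In naive and central memory 15 of 18 members were positive (Rapgef6 0.22 ± 0.12). In cell cycle, in sums without the cycling Mki67High cells, 30 of 37 were negative (Tubb5 -0.18 ± 0.09, Stmn1 -0.34 ± 0.18). Without isotype replicate 2 and without anti-PD-1 replicate 1 naive and central memory had 9 and 8 positive members and did not pass. Their camera adjusted p values in all libraries were 0.00920 and 0.000786, with an adjusted p = 0.672 and 0.638 with an estimated correlation. Over all genes 0 members of the 6 lists passed, and adjusted over the list alone 1 B cell marker and 1 gamma-delta T marker did, Cd74 and Trdv4 (-4.50). In lists that did not pass camera Areg passed over the list alone in Treg suppression and in Th2, and Il5 (3.15) in Th2. With the replicate block camera called cell cycle, naive and central memory and B cell markers, and over the list alone Cd74 -0.57 and, in the Th2 list, Il5 3.26 still passed by log2 difference, and Areg and Trdv4 did not. Trdv4 and Il5 were named after their values were seen. In replicates 1 to 3 Il5 had 0, 2 and 3 UMIs in isotype and 1, 3 and 9 in anti-PD-1 Treg_Norm cells. Treg_KO cells had 0 Il5 UMIs. In Tconv of isotype replicate 3, 210 of its 223 UMIs lay in 1 cell, so the Il5 difference rests on few cells.

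Treg_KO and Treg_Norm cells, which shared the same lungs, differed widely. The labels do not say how cells were put in these deposited classes, so the differences describe how the classes stand apart, whatever part the loss of PD-1 has in them. Were the classes drawn from expression, p values between them would be too small. The 12 largest rises were each seen in 6 of 6 libraries. Klf2, a factor of T cell egress, rose from 202 ± 115 to 1794 ± 383 CPM (SD, n = 6), a log2 fold of 3.28 ± 0.09. The surface gene Ly6c1 rose from 12.6 ± 3.70 to 279.6 ± 30.8 (4.52 ± 0.13). Satb1, Bach2 and Bcl2, genes of a chromatin organiser, a repressor of effector fates and a survival factor, had log2 folds of 3.34 ± 0.10, 3.47 ± 0.17 and 3.28 ± 0.12. Igfbp4, Tubb2a, Atp1b1, Nsg2, Rflnb, Patj and St8sia6 completed them, with log2 folds of 3.39, 3.82, 3.83, 3.64, 3.43, 3.30 and 3.15.

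The largest falls were in genes with few or no UMIs in Treg_KO cells. Of the 12 named, 11 had 0 UMIs in the Treg_KO cells of all 6 libraries and were at least 20.7-fold to at least 89.6-fold lower, against a floor of 3 counts over the group (0.980 CPM of all UMIs). Adam8, Ccdc184, Pvrig, Ednrb and the chemokine receptor gene Ccr3 were at least 89.6-fold, 48.4-fold, 39.4-fold, 30.99-fold and 26.4-fold lower. Rnase4, Jcad, Tnfrsf8, Acot11, Ccr1 and Igfbp7 were at least 25.7-fold, 22.2-fold, 21.6-fold, 21.5-fold, 20.8-fold and 20.7-fold lower. Tff1 had 3944 UMIs in Treg_Norm and 1 in Treg_KO cells, a ratio of CPM of 514 (exact interval 92.1 to 20288).

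Grouped by list, 18 of 18 measured members of Treg suppression fell in Treg_KO cells, such as the granzyme gene Gzmb (-6.80 ± 0.17), Klrg1 (-7.56 ± 0.21), Fgl2 (-7.24 ± 0.24) and Tigit (-4.66 ± 0.12), with a camera adjusted p of 1.15e-20. In co-inhibitory and exhaustion 15 of 17 fell and 1 rose (Pdcd1 -2.91 ± 0.09, Id2 -3.01 ± 0.09), in Th1 and cytotoxic 16 of 19 fell and 1 rose (Ccl5 -5.54 ± 0.17), and in Th2 9 of 9 fell (Areg -2.68 ± 0.11, Ccr4 -4.76 ± 0.26). Their camera adjusted p values were 5.36e-13, 3.65e-11 and 7.53e-07, and these 4 lists each had an adjusted p = 0.0412 with an estimated correlation. In class I antigen presentation 13 of 15 fell (Tap1 -1.44 ± 0.08, Psmb9 -1.32 ± 0.08), with a camera adjusted p of 2.26e-09 and an adjusted p = 0.0449 with an estimated correlation. Dendritic cell markers fell in 3 of 3 genes, with an adjusted p = 0.0449 with an estimated correlation. In naive and central memory 16 of 18 rose and 1 fell, such as the homing receptor gene Ccr7 (1.91 ± 0.05) and Foxp1 (2.22 ± 0.08), with a camera adjusted p of 1.28e-18 and an adjusted p = 0.0449 with an estimated correlation. In dissociation and heat-shock stress 16 of 25 rose and 4 fell (Jun 2.49 ± 0.09, Fos 1.67 ± 0.07), with a camera adjusted p of 4.10e-07 and an adjusted p = 0.0412 with an estimated correlation. Adjusted over the list alone, the counts were the same except for 17 rises in each of the last 2 lists. Leaving out any library, the 16 lists that camera called stayed called, but 0 to 4 were with an estimated correlation, against 8 in all libraries.

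In the other 8 lists that camera called, the call was lost with an estimated correlation. With the replicate block 10 lists rather than 8 were called with an estimated correlation. Interferon response had 39 of 45 falls (Ly6a -2.77 ± 0.07, Cxcl10 -3.89 ± 0.13), with an adjusted p = 0.0546 with an estimated correlation. Chemokine receptors and tissue retention had 16 of 20 falls (Cxcr3 -5.74 ± 0.21, Ccr8 -4.13 ± 0.12), with an adjusted p = 0.0596 with an estimated correlation. Treg identity had 13 of 18 falls and 4 rises, with Tnfrsf9 at -3.23 ± 0.07, Gpr83 at 5.38 ± 0.21 and Foxp3 at -0.999 ± 0.070 (adjusted p = 0.0879 with an estimated correlation). TCR and activation response had 13 of 21 falls (Icos -3.01 ± 0.10), glycolysis 15 of 19 (Aldoa -1.52 ± 0.07, Tpi1 -2.43 ± 0.15) and Th17 6 of 7 (Rora -3.36 ± 0.10), with an adjusted p = 0.0554, 0.0665 and 0.0955 with an estimated correlation. Beside these, B cell markers fell in 5 of 5 genes (Igkc -5.30 ± 0.29, Cd74 -3.34 ± 0.11) and macrophage and monocyte markers in 3 of 5 (Plac8 -5.60 ± 0.15), with an adjusted p = 0.0596 and 0.123 with an estimated correlation. Lists of lipid metabolism did not pass camera, with 8 falls and 3 rises among 22 cholesterol synthesis genes (adjusted p of 0.427) and 9 falls and 1 rise among 18 fatty acid oxidation genes (adjusted p of 0.0726).

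Between the classes edgeR called 4434 of 9003 genes, 2077 higher and 2357 lower in Treg_KO cells, and DESeq2 called 3571. Pdcd1 was at 687 ± 108 CPM in Treg_Norm and 91.7 ± 26.6 in Treg_KO cells, with an adjusted p of 1.70e-28 in edgeR. Without the TMM factor 23.8% of the calls were higher rather than 46.8%, with the median log2 fold of all genes at -0.29. With every cell thinned to 2000 UMIs 2657 of 6784 genes were called, 2575 of them among the 4434.

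The interaction of class and treatment asked whether the antibody acted differently on Treg_KO and Treg_Norm cells, and edgeR called 6 of 9003 genes. The chemokine gene Ccl5 had a log2 difference of 2.95 ± 0.49 (adjusted p = 0.00162 in edgeR), from 3, 1 and 2 UMIs in the Treg_KO cells of the isotype libraries and 17, 4 and 17 in those of the anti-PD-1 libraries. The club cell gene Scgb1a1 had -5.25 ± 0.97 (adjusted p = 0.00897 in edgeR), with 308 of its 312 UMIs in isotype replicate 3 in 1 cell, and 0.27 without that library. The receptor segments Trbv26, Trbv4, Trav10n and Trbv29, named after their values were seen, had -1.85 ± 0.30, -2.23 ± 0.46, -4.81 ± 0.99 and 1.80 ± 0.38. Of the genes that did not pass, Pdcd1lg2, Mtx1, Spata6 and Pdcl3 had 1.63 ± 0.50, 1.149 ± 0.338, 1.22 ± 0.40 and 0.92 ± 0.31. Pim2, Ifit1, St6gal1 and Snapc2 had -1.06 ± 0.29, -0.82 ± 0.23, -1.19 ± 0.34 and -1.24 ± 0.39, Pdcd1 -0.22 ± 0.21 and Foxp3 0.04 ± 0.14. With the replicate number in place of the library as the block edgeR called 0 genes (361 at an unadjusted p under 0.05). That fit does not pair the classes of a library. With the library as the block DESeq2 called 0 (87), and 0 of 25 lists passed camera with either block. Adjusted over the list alone Ccl5, Pdcd1lg2, Pim2 and Ifit1 passed, each in 1 list, and 0 with the replicate block.

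Tregs made up 11.7% ± 4.28 of the cells of isotype and 11.3% ± 3.09 of those of anti-PD-1 libraries (SD, n = 3 each; exact permutation p = 1), a difference that changed sign without isotype replicate 2 (1.85 percentage points) or anti-PD-1 replicate 1 (1.27). The cycling share of thinned Tregs was 6.78% ± 1.12 and 5.61% ± 2.02 (exact permutation p = 0.5), a difference of -1.17 percentage points that shrank to -0.0994 without anti-PD-1 replicate 1. Without thinning it was 10.4% ± 1.001 and 7.83% ± 0.935, lower in 3 of 3 pairs (exact permutation p = 0.1, the smallest this design allows). Treg_KO cells made up 14.4% ± 4.72 and 17.7% ± 11.9 of the Tregs (exact permutation p = 0.9), with 30.9% in anti-PD-1 replicate 1, without which the difference was -3.23 percentage points. A Pdcd1 UMI was detected in 56.3% ± 6.53 and 50.4% ± 14.2 of thinned Tregs (exact permutation p = 0.6), lower in 2 of 3 pairs, and in 31.8% ± 1.25 and 31.3% ± 3.55 of thinned Tconv_PD1High cells (exact permutation p = 0.8). In thinned Treg_Norm cells only it was detected in 63.7% ± 4.74 and 58.1% ± 10.6 and in Tregs that were not thinned in 71.5% ± 6.86 and 63.9% ± 13.3 (exact permutation p = 0.4 and 0.5), lower in 3 of 3 pairs in both. In thinned Tregs alone in their clone it was detected in 43.8% ± 3.26 and 40.9% ± 7.98 (exact permutation p = 0.7), lower in 1 of 3 pairs. Tconv_PD1High cells made up 35.0% ± 1.35 and 33.3% ± 5.01 of Tconv (exact permutation p = 0.8). Without anti-PD-1 replicate 1 the differences in thinned Tregs, in thinned Tconv_PD1High cells and in this share changed sign, to 1.23, 0.310 and 1.03 percentage points, and the middle one of the 3 also without anti-PD-1 replicate 3 (0.549). None of the 9 shares passed, clone shares included, with an adjusted p of 1 for each in a design where an exact permutation p cannot fall below 0.1.

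Receptor clones of at least 2 cells held more of the Treg_Norm, Tconv_PD1High and Mki67High cells than of the other classes in each library. Per library they held 14.8% to 69.3% of Treg_Norm, 15.2% to 44.4% of Tconv_PD1High and 16.05% to 64.81% of Mki67High cells, whose order differed between libraries. They held 0.311% to 2.66% of Tconv_PD1Low and 0% to 6.25% of Treg_KO cells, 13 of 675 in all and 7 of them in isotype replicate 3. In equal numbers of cells, clones held 42.1% ± 15.5 of Tregs in isotype and 29.2% ± 21.3 in anti-PD-1 libraries (SD, n = 3 each; exact permutation p = 0.5), lower in 3 of 3 numbered pairs, for which the exact sign-flip p was 0.25. In Tconv they held 12.7% ± 5.75 and 10.6% ± 5.27 (exact permutation p = 0.5), and in all cells 18.6% ± 8.84 and 14.9% ± 8.43 (exact permutation p = 0.5). Both were also lower in 3 of 3 numbered pairs (exact sign-flip p = 0.25 for each). Without anti-PD-1 replicate 1 the difference shrank from -12.9 to -2.50 percentage points in Tregs and turned to 0.944 in Tconv and to 1.08 in all cells. This leaves isotype replicate 1, the lowest isotype library in each of these, without its numbered pair. In all cells it stood at 8.48%, against 24.7% and 22.7% in isotype replicates 2 and 3. The largest clone held 134 cells, in isotype replicate 2, of which 89.6% were Tregs.

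**Figure D3:**
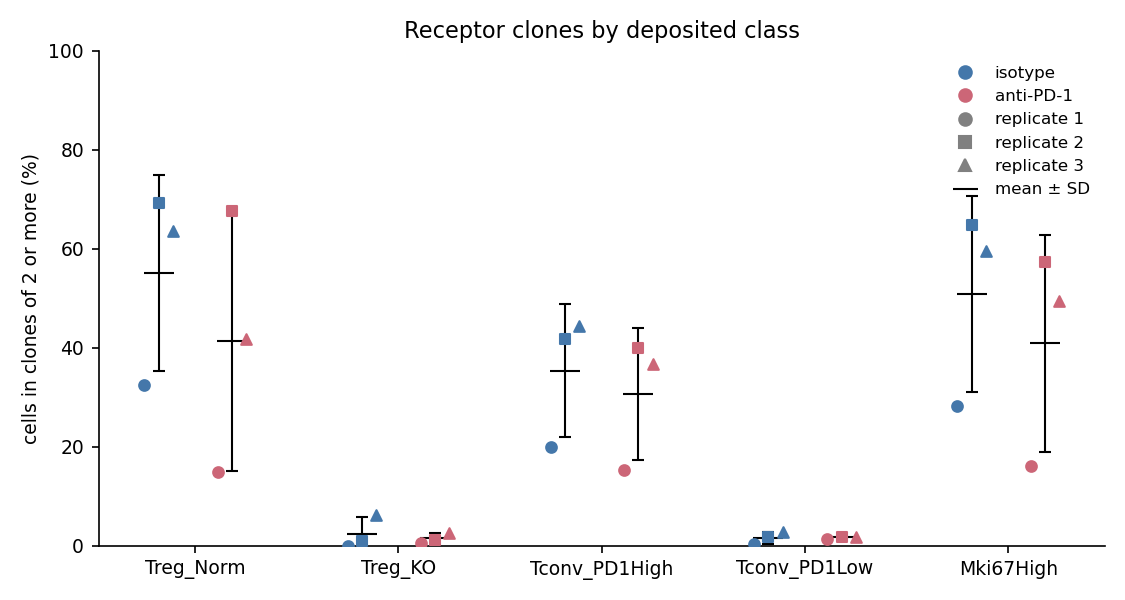
Share of cells (%) in receptor clones of at least 2 cells of the same library, by deposited class, with 1 point per library, colour for the antibody, marker shape for the replicate and bars for the mean ± SD of 3 libraries. Per library the share is 14.8% to 69.3% in Treg_Norm and 0.311% to 2.66% in Tconv_PD1Low and 0% to 6.25% in Treg_KO cells.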

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

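The tests of single cells, of shared receptors and of clones that hold both Treg classes, and the division of the genes called with the replicate block into parts, were chosen only after the results they concern were seen.

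The interaction in edgeR called 6 genes for a different effect of treatment in Treg_KO and Treg_Norm cells. They were Trbv26 (log2 difference -1.85 ± 0.30, adjusted p = 0.00162), Ccl5 (2.95 ± 0.49, 0.00162), Scgb1a1 (-5.25 ± 0.97, 0.00897), Trbv4 (-2.23 ± 0.46, 0.0341), Trav10n (-4.81 ± 0.99, 0.0341) and Trbv29 (1.80 ± 0.38, 0.0400). In Treg_KO cells 308 of the 312 Scgb1a1 UMIs of isotype replicate 3 lay in 1 cell, and 16 of the 17 Ccl5 UMIs of anti-PD-1 replicate 1. Of the 17 Ccl5 UMIs of anti-PD-1 replicate 3, 10 lay in 1 cell. Receptor segments were found in few Treg_KO cells per library, 0 to 2 for Trav10n, 1 to 8 for Trbv26 and Trbv4 and 1 to 9 for Trbv29. Their calls may thus reflect which few receptors were sampled. Of the 10 splits of the 6 libraries 4, the real one included, gave at least the 6 genes of the real one, and the highest other gave 33. That split set isotype replicate 1 with anti-PD-1 replicates 1 and 3, and why it gave more genes than the real one was not tested. With the replicate number in place of the library as the block 0 genes passed in edgeR (361 at an unadjusted p under 0.05). That fit does not pair the classes of a library, so its count does not decide on the 6 calls. With the library as the block 0 passed in DESeq2.

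The effect of treatment differed between Tregs and Tconv in camera for 6 lists, 0 of which held with an estimated correlation and 2 to 5 of which stayed called leaving out a library. The adjusted p values were 0.000786 for cell cycle, 0.000786 for B cell markers, 0.00920 for naive and central memory, 0.0289 for endothelial and stromal markers, 0.0492 for Th1 and cytotoxic and 0.0492 for gamma-delta T markers. The last 3 had an adjusted p = 0.568, 0.638 and 0.568 with an estimated correlation, and B cell markers an adjusted p = 0.568 with an estimated correlation. In Th1 and cytotoxic the mean of 0.02 and the median of -0.12 differed in sign.

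Treg_KO cells differed from Treg_Norm cells in 4434 genes. Fewer UMIs per Treg_KO cell are argued against as the whole cause, since 58.1% of the called genes were still called after thinning. A candidate explanation is a resting against an activated state shared with Tconv: across 8972 genes, which are not independent, the log2 folds correlated with those of Tconv_PD1Low over Tconv_PD1High at a Spearman rho of 0.800. Both contrasts part deposited classes that differ in Pdcd1 (log2 folds of -2.91 and -5.33). Were the classes drawn from expression, such a correlation could come from how they were drawn. Clones with both classes numbered 4, where random classing of the Tregs of each library gave 132 to 176 in 1000 draws. As 13 of 675 Treg_KO cells lay in clones of at least 2 cells, this count restates that they were rarely in clones. It does not decide on loss of Pdcd1 at random among the cells of grown clones. Loss before clones grew would also leave few such clones. Neither the transgene nor the labels show how cells were classed, so what part PD-1 loss has in these differences stays open.

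Receptors with both chains identical occurred in replicates 2 and 3 of the same antibody, 44 in the isotype and 99 in the anti-PD-1 libraries. Reads of a cell assigned to both libraries are argued against by 0 cells with the same barcode and receptor in both, and receptors that arise independently in many mice by at most 1 shared receptor in any of the other 13 pairs of libraries. An even division of 1 cell suspension is argued against, since 14.3% of the shared clones of at least 10 cells were within 5 times of each other in size. The same animals, and whole cells carried over or assigned to the wrong library, cannot be told apart for the 143 shared receptors, since the labels name no animals. Replicates 2 and 3 are therefore not shown to be independent.

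With the replicate block 4 genes were called in Tregs, where 0 were called without it (178 at an unadjusted p under 0.05, DESeq2 2). Over the 4 together, 1 remained called without the highest cell of each gene and 1 with 1 cell per receptor clone, so neither UMIs of single cells nor clonal expansion, the latter predicted before its test, is decided for the whole. In parts divided after these values were seen, UMIs of single cells are a candidate explanation for Il2 and Ccl1, of which 0 remained called without the highest cell, both falling below the expression filter, while 1 remained with 1 cell per clone (Ccl1, -3.55 ± 0.25 before and -3.93 ± 0.25 after, with Il2 again below the filter and so not tested). For Trav8-1 and Trav8n-2, 1 remained without the highest cell (Trav8-1, 2.19 ± 0.23) and the other had a log2 fold no smaller (2.42 ± 0.32, adjusted p = 0.0951), which argues against single cells, and 0 remained with 1 cell per clone, where their log2 folds went from 1.94 ± 0.21 and 1.96 ± 0.24 to 0.69 ± 0.22 and 1.47 ± 0.29, so clonal expansion stays open for them. Among the 4 splits that part all 3 numbered pairs, the real one gave 4 genes and the highest other 1. Only the real one gave as many as 4, with too few splits for a share under 0.05.

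For the other treatment comparisons the 10 splits of the libraries are too few for a share under 0.05. In Tregs and in Tconv edgeR called 0 genes in the real split and at most 0 in the others, with 178 and 180 genes at an unadjusted p under 0.05, and DESeq2 called 2 and 0. For their interaction the real split gave 0 (373 at an unadjusted p under 0.05, DESeq2 1) and the highest other 1. In Treg_Norm, Treg_KO, Tconv_PD1High, Tconv_PD1Low and Mki67High cells edgeR called 0 genes in the real split, with 219, 152, 233, 183 and 158 at an unadjusted p under 0.05, and DESeq2 called 2, 0, 0, 0 and 0. The highest other splits gave 1, 2, 0, 0 and 99. The last set isotype replicate 1 with anti-PD-1 replicates 1 and 3, and the cause of its count was not tested. In cycling cells the blocked fit called 3, Trbv17 (-3.82), Trav5-1 (-4.42) and Hspa1a (-3.49). The blocked fit also called 6 in Treg_Norm, Il2 (8.75), Trbv13-1 (0.66), Trav6d-4 (-2.31), Trav8n-2 (2.00), Trav8-1 (2.08) and Ccl1 (-3.57), and 1 in Treg_KO, Gm42418 (0.38). These genes and the calls of DESeq2 in Treg_Norm, Trav6d-4 (-2.26) and Trav8-1 (2.09), are named with log2 folds after their values were seen. In the blocked fit the highest of the other splits that part all 3 numbered pairs gave 0 genes in Treg_Norm, 1 in Treg_KO, as many as the real split, 1 in Tconv_PD1High, where the real split gave 0, 0 in Tconv_PD1Low and 0 in Mki67High. Between the Treg classes 32 swaps of whole class sums within libraries were made, the real classing counted among them. Only the real classing gave 4434 genes, and the highest other gave 0. The swaps show that the classes differed in the same way across libraries. They do not test how cells were classed, and classes drawn from the same expression values would give such calls by construction.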

How the results depend on the processing

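The alternatives with 1 cell per clone, the highest cell of each gene left out, the replicate block joined with either, with an estimated correlation or with summed replicates, replicates 2 and 3 only or summed, and thinned cells, and for gene lists leaving out each library and Treg_Norm cells only, were chosen only after the results were seen. The comparison of Tregs with and without a Pdcd1 UMI was not run, since the deposited annotation gives Treg classes, nor was a minimum of 2 UMIs of the transgene, since 0 genes are named for it. The depth of 81 to 172 Treg_KO cells per library limits every result in them.

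Between the Treg classes the count stayed within 1.5 times of 4434 under each alternative (4015 to 4140 leaving out a library) except 2657 with cells thinned, where fewer genes were tested, and lists fell from 16 to 8 with an estimated correlation and 10 with it and the replicate block. In Tregs the count went from 0 (178 at an unadjusted p under 0.05 in edgeR) to 2 in DESeq2, 4 with the replicate block, 1 with it and 1 cell per clone (Ccl1 -3.93), 1 with it and the highest cell left out (Trav8-1 2.19), 1 in replicates 2 and 3 only (Ccl1 -3.53) and 12 with the block and replicates 2 and 3 summed, but stayed at 0 with these summed and no block. In Tconv it went from 0 (180, DESeq2 0) to 1 in replicates 2 and 3 only (Lgals3 1.01). For Tregs minus Tconv it went from 0 (373) to 1 in DESeq2, 1 with Foxp3 UMIs defining Tregs (Calca -1.43) and 11 in replicates 2 and 3 only, and ranged over 0 to 5 leaving out a library, with 1 without anti-PD-1 replicate 1 (Cxcl2 3.02) and 5 without anti-PD-1 replicate 2 (Trbv12-1 1.08, Trbv15 1.48, Mt1 -0.86, Trav8n-2 2.41 and Trav4-4-dv10 1.66).

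The 6 genes of the interaction of class and treatment became 0 in DESeq2 (87 at an unadjusted p under 0.05), 0 with the replicate block alone, with 1 cell per clone (0) or with the highest cell left out (0), 10 with no filter, 3 with Foxp3 UMIs (Trbv19 -1.38, Trbv26 -1.75 and Ifit1 -1.58), 3 with 1 cell per clone (Trbv26 -1.80, Ccl5 2.97 and Scgb1a1 -5.09), 2 without the highest cell (Trbv26 -2.24 and Trbv29 4.92), 12 in replicates 2 and 3 only and 1 with thinned cells (Trbv26 -2.06), and ranged over 4 to 7 leaving out a library. Lists called in Tregs (11), in Tconv (7) and in their difference (6) fell to 0 with an estimated correlation, alone or with the block, and in directional fry, and those of the difference to 3 with the block. In fry without regard to direction they were 2, 0 and 0, those in Tregs being Th2 and B cell markers (adjusted p = 6.74e-06 and 0.00601), with 0 in Tregs with the block. Leaving out a library, lists called were 1 to 13 in Tregs, fewest without anti-PD-1 replicate 1, 1 to 9 in Tconv, fewest without isotype replicate 2, 3 to 6 in their difference, 16 between the Treg classes each time and 0 to 2 for class and treatment, with 2 without anti-PD-1 replicate 2. In Treg_Norm cells only they were 10, and 12 with the block. The genes in brackets, with log2 folds, were named after their values were seen. For class and treatment lists went from 0 to 1 in directional fry. The cause of these changes was not tested.

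Of the values of named genes under the alternatives, 580 of 585 in Tregs, 421 of 436 in Tconv, 304 of 306 in their difference, 1008 of 1008 between the Treg classes and 190 of 214 for class and treatment kept direction and side of the threshold. Log2 folds that reversed were those of Foxp3 in Tregs (-0.0746 with replicates 2 and 3 summed, -0.0760 with the block as well, -0.0931 to 0.14 leaving out a library), of Foxp3 in Tconv (0.00191 in replicates 2 and 3 only, -0.34 to 0.22) and of Foxp3 in their difference (-0.12 to 0.46). Pdcd1 in Tconv reversed to -0.00698 with Foxp3 UMIs, -0.00617 with the block, -0.10 with 1 cell per clone, -0.10 with both, -0.00872 with the block and the highest cell left out, -0.0238 with replicates 2 and 3 summed and -0.0435 with these and the block (-0.17 to 0.19 leaving out a library), and Gzmk in Tconv to 0.0419 and 0.0366 with 1 cell per clone, alone and with the block. For class and treatment, Foxp3 reversed to -0.00518 with 1 cell per clone, -0.0235 with it and the block and -0.0221 in replicates 2 and 3 only (-0.0957 to 0.16 leaving out a library), Pdcd1 to 0.20 with thinned cells and Scgb1a1 ranged over -6.58 to 0.27 leaving out a library, positive without isotype replicate 3.

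Leaving out a library, differences of shares ranged over -2.41 to 1.85 percentage points for Tregs, -3.23 to 8.37 for Treg_KO, -12.9 to 1.23 for Tregs with a Pdcd1 UMI, -2.63 to 0.549 for Tconv_PD1High cells with one, -3.90 to 1.03 for the Tconv_PD1High share, and -8.74 to 1.08 and -5.39 to 0.944 for expanded clones in all cells and in Tconv, each with both signs. They kept 1 sign for expanded clones of Tregs (-23.8 to -2.50) and the cycling share (-2.10 to -0.0994). In the 5 classes 73 of 92 counts of treated against isotype cells stayed at 0, and the highest was 44, in Treg_Norm with the block and replicates 2 and 3 summed.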

Other observations

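The tables of Treg clones by Pdcd1 and of reference labels were chosen only after the data were seen.

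Pdcd1 was found in every large Treg clone. In 82 clones of at least 6 Tregs, 1137 cells in all, Pdcd1 UMIs were found in 57.7% to 100% of the cells of each clone, with a median of 91.3%, and 0 clones had none. None of these clones came from anti-PD-1 replicate 1. Treg_KO cells were rarely in clones, 13 of 675 in clones of at least 2 cells, and 78.3% of all Treg_Norm cells had a Pdcd1 UMI. Clones of this size with no Pdcd1 UMI were therefore hardly possible, so the count does not tell how PD-1 bears on clone growth. Of the Tregs alone in their clone 56.2% had a Pdcd1 UMI, and of the Treg_Norm cells among them 69.6%. In Tconv_PD1Low cells, a class named for low PD-1, the share was 1.56% to 3.80% per library, at a median depth of 4549 UMIs against 5121 in Treg_Norm cells. Gzmb, the granzyme B gene, was found in 24.5% to 45.5% of Treg_Norm and 0% to 3.42% of Treg_KO cells, against 0.308% to 2.36% of Tconv_PD1Low cells. The cytokine gene Il10 was found in 11.9% to 18.6% of Treg_Norm and 0% to 1.23% of Treg_KO cells, against 0.0220% to 0.265%.

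For replicate 1 the deposited annotation also gives a reference label per cell. NKT labels were given to 44.5% of Treg_Norm cells in the isotype and 34.9% in the anti-PD-1 library, and to 43.2% and 36.4% of Tconv_PD1High cells. In Mki67High cells they went the other way, at 21.8% and 25.9%. Treg_KO cells had 0% in both libraries, and Tconv_PD1Low cells 0.0718% and 0.0440%. ILC labels were given to 17.9% and 13.3% of Treg_Norm cells. With 1 library of each antibody no test was made, and the exact intervals in Treg_Norm cells were 39.8% to 49.4% and 30.1% to 39.9% for NKT labels.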
